A study of Homo sapiens with 4 samples.

How the data were processed

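RNA of GIST-T1 cells was measured on 4 one-colour (Cy3) Agilent whole-transcriptome arrays of design 039494. Per the labels, 2 arrays hold cells given a negative control oligonucleotide and 2 hold cells given a miR-186 inhibitor. Cells were taken 48 h after transfection, 100 pmol of oligonucleotide was given to 3000000 cells, and 100 ng of RNA went into each labelling reaction, per the labels' protocols. Each array has 62976 spots, of which 58717 are not control spots.

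The deposited spot intensity values came from Agilent Feature Extraction 10.7.3.1, per the file headers (10.7 in the submitters' processing notes). Per the file headers, the processed intensity is background-subtracted and detrended within 1 array, with a surrogate value for spots not above background, and is not scaled between arrays. The deposited series value table repeats the processed intensity: its ratio to the scanner value lay between 0.995 and 1.00 for each of the 62976 spots of each array, so its scale is linear and it is neither centred nor a ratio. Its column medians were 11.3 and 10.6 for the controls and 18.8 and 14.45 for the inhibitor arrays. Probe coordinates in the files are on hg19, per the file headers, and are given only as the files give them.

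Expression was computed as log2 of the processed intensity minus the 75th percentile of the array's non-control spots. That percentile was an intensity of 215.5 and 217.6 on the control arrays and 271.2 and 270.7 on the inhibitor arrays. Spots flagged as non-uniform or population outliers were left out, 301 to 346 per array, which removed 7 of 50599 probes. No spot was saturated. Spots of one probe were averaged (902 probes have 10 spots). A probe was kept where it was well above background on both arrays of at least 1 group, which left 22961 probes. Well above background means that at least 0.5 of the probe's spots on an array carried that mark. Each gene was represented by the passing probe with the highest mean, and 4240 of the 17173 genes tested had more than 1 passing probe. Names were updated with a RefSeq gene table of GRCh38.p14, used for names only. Of the probes, 28172 were matched by accession, 2617 by symbol and 620 by synonym, and 19183 kept the name in the file.

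The 2 groups were compared with limma 3.58.1 (lmFit and eBayes, constant prior variance, two-sided) in R 4.3.3. Benjamini-Hochberg adjustment ran over all genes tested, with adjusted p under 0.05 as the threshold. There are 2 residual degrees of freedom per gene. With an array left out, or with a replicate block, there are fewer, so a result can be lost there through lower power alone. The 29 gene lists were compared with all other genes by camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists with at least 3 measured members. Groups, tests, lists, the naming rule and the settings to be varied were set before the data were examined.

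A probe not well above background on any array of a group has only a bound there, written as "at least N-fold". The brighter group's mean was set against the dim group's mean of, per array, the higher of the probe's own value and the lowest value among probes well above background. The files show all 4 arrays on 1 slide and in 1 scan, controls at positions 1 and 2 and inhibitor arrays at positions 3 and 4. A slide or scan block was therefore not possible, and position and group cannot be told apart. Nothing in the labels says that the 2 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

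The rule for named genes took the 12 largest differences each way among genes past adjusted p 0.05. Such a gene had to be well above background on both arrays of the brighter group, carry an approved-style symbol and have both inhibitor arrays on the same side of both controls. Where fewer passed, the rule filled up to 12 at unadjusted p under 0.05, named as not passing. Of each list, up to 4 members with the smallest adjusted p are named. ZRANB2, KIT and the 5 genes of the study list are given on every array. A further 17 genes, well above background on all 4 arrays and past 0.05 with an intensity trend in the prior, were chosen after their values were seen, as were 3 further members of the immediate early and heat shock list. Some genes that these rules name are not reported here. The planned test of miR-186-5p sites in 3' UTRs was left out, since no transcript or genome sequence was used here.

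Alternatives were quantile normalization, median centring, normexp background correction (offset 50), the deposited value table, other filters, other probe rules, an intensity trend or robust prior, a replicate block, other thresholds, an unmoderated test, each array left out, and other list tests. Scaling to the spike-in probes and further settings of the intensity-trend fit were added after seeing the data. The fits were tested on simulated data for this comparison, with 17173 genes and SDs drawn from the residual SDs estimated for real genes of like mean. Those estimates rest on 2 residual degrees of freedom, so the simulated SDs carry their sampling error. The counts of genes called need not hold for the real fit. Of 50 bright genes changed by 1 on the log2 scale, the constant prior called 28 and the intensity trend 33. Of 50 changed by 2, each called 48. Of 50 changed by 3, the constant prior called 45 and the intensity trend 50. Of 50 changed by 0.5, the constant prior called 7 and the intensity trend 24. False calls numbered 7 and 8. A list of genes all moved by 0.3 had a camera adjusted p = 7.04e-28 with the preset correlation and adjusted p = 0.568 with an estimated correlation. The simulated noise was independent between genes, so this run does not test the preset correlation for lists whose genes vary together. Figures were drawn with matplotlib 3.10.9.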

Results

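GIST-T1 is an established human cell line from a gastrointestinal stromal tumour, a sarcoma of the gut wall driven in most cases by activated KIT. Gene expression was measured by one-colour Agilent arrays in 2 control samples and 2 samples given an inhibitor of miR-186, a synthetic oligonucleotide meant to block that microRNA, 48 h after transfection. Between 27997 and 30382 of 58717 non-control spots per array were well above background. Over 21442 probes well above background on all 4 arrays, log2 values correlated across probes at r = 0.997 between the control arrays and 0.994 between the inhibitor arrays. Between groups r was 0.992 to 0.993. Probes are not independent replicates. Values below are log2 intensities relative to the array's 75th percentile, and differences are inhibitor minus control with n = 2 per group.

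The comparison asks which mRNAs differ when miR-186 is blocked. The 5 genes that the study singled out on these samples all lay higher on both inhibitor arrays than on both controls. IGFBP3, a binding protein of insulin-like growth factors, was at -2.53 ± 0.01 (SD, n = 2) in controls and -1.12 ± 0.09 with the inhibitor, 2.66-fold higher. EFEMP1, an extracellular matrix glycoprotein, was at -1.60 ± 0.01 and -0.58 ± 0.01, or 2.02-fold. CXCR4, a chemokine receptor, was at -1.27 ± 0.03 and -0.50 ± 0.04, or 1.71-fold. AKT2, a serine/threonine kinase of the PI3K pathway, was at 0.98 ± 0.06 and 1.79 ± 0.06, or 1.76-fold. MET, the receptor of hepatocyte growth factor, was not well above background on either control array and was at least 1.44-fold higher with the inhibitor.

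With limma's constant prior the adjusted p of these genes was 0.0574 for IGFBP3, 0.0589 for EFEMP1, 0.0772 for CXCR4, 0.0890 for AKT2 and 0.0983 for MET, so none passed over all genes. All 5 passed when adjusted over the list alone, which is not independent evidence because the study chose the list on these samples. With an intensity trend in the prior, IGFBP3 (adjusted p = 0.0172), EFEMP1 (0.0186), CXCR4 (0.0312) and AKT2 (0.0146) passed and MET (0.0935) did not. AKT2 has 3 probes, and the other 2 gave differences of -0.28 and -0.23. Its mean over the 3 probes differed by 0.10 (adjusted p = 0.371). On hg19 the AKT2 probe used lies on chromosome 19 from 40738703 to 40738762 (minus strand), and the other 2 lie at 40736224 to 40736283 and 40761075 to 40761134. The IGFBP3 probe lies on chromosome 7 from 45952608 to 45952667 and the MET probe on chromosome 7 from 116438290 to 116438349. The EFEMP1 probe lies on chromosome 2 from 56093788 to 56093847 and the CXCR4 probe on chromosome 2 from 136871953 to 136872012.

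**Figure D1:**
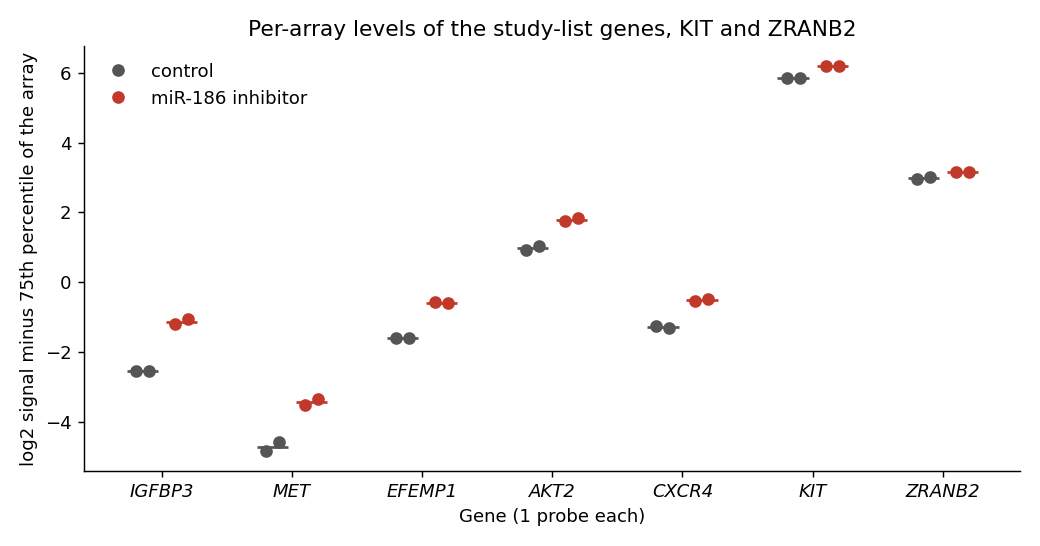
Log2 signal minus the array's 75th percentile (y axis) of 7 genes (x axis) on each of the 2 control arrays (grey points) and 2 inhibitor arrays (red points), with group means as bars. IGFBP3, EFEMP1, AKT2 and CXCR4 differ by 0.78 to 1.41, KIT by 0.34 and ZRANB2 by 0.17, and MET, dim on both control arrays, has only a bound.

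KIT, the receptor tyrosine kinase that defines the tumour type, was at 5.85 ± 0.01 in controls and 6.19 ± 0.01 with the inhibitor, a difference of 0.34 (adjusted p = 0.125). With an intensity trend the adjusted p was 0.0358. The other 2 KIT probes differed by -0.02 and 0.02, and the mean over its probes by 0.11. ZRANB2, whose gene hosts MIR186, was at 2.98 ± 0.05 and 3.15 ± 0.01, a difference of 0.17 (adjusted p = 0.238). Mature miR-186 was not measured, so the block itself has no direct readout on these arrays. Of 18 genes reported as miR-186 targets before, 16 were measured, and their median difference was 0.01, their mean -0.02 and the test upward (camera adjusted p = 0.951). The members with the smallest adjusted p were CCND1 (difference 0.20), YAP1 (-0.16), PTTG1 (-0.17) and PAWR (-0.19), none of which passed. No member passed when adjusted over the list alone.

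Over all 17173 genes tested, limma with a constant prior called 0 genes higher and 0 lower at adjusted p under 0.05, and the smallest adjusted p was 0.0526. At an unadjusted p under 0.05 there were 1894 higher and 1720 lower genes. The 2 inhibitor arrays lay on one side of both controls for 9906 genes, 57.7% of those tested, where chance gives 33.3%. The planned intensity-trend fit called 173 genes higher and 131 lower, normexp background correction 143 and 80, quantile normalization 6 and 0, and the unmoderated test 0 and 0. Other scalings turned or overwhelmed that balance: median centring called 227 higher and 463 lower (134 and 448 with the trend), and scaling to the spike-ins, added after seeing the data, 14745 and 22. Between 47.7% and 51.7% of spots per array were well above background, so the median lies near the background. Median intensities were 14.8 and 14.0 on the control arrays and 22.9 and 18.5 on the inhibitor arrays. Centring on them moved the median difference of all genes to -0.21. That offset lowers every difference, so it does not account for the 227 higher calls. The 2 inhibitor medians also lay apart, while the 75th percentiles of those arrays were 271.2 and 270.7. Centring therefore moved the 2 inhibitor arrays by unequal amounts, and what this did to the counts was not tested. The intensity-trend fit was also run with each array left out, where the spread comes only from the group that keeps both arrays. Over probes, the SD of the difference was 0.276 between the inhibitor arrays and 0.189 between the control arrays. Counts from those fits therefore depend on which pair is left.

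Among genes well above background on all 4 arrays, CHMP4B, a subunit of the ESCRT-III membrane scission complex, was 3.84-fold higher. It was at 2.07 in controls and 4.02 with the inhibitor (difference 1.94, limma adjusted p = 0.0526, 0.00205 with the trend). CLSTN3, a calsyntenin, differed by 1.84, and by 1.73 at its second probe. ARHGEF25, a guanine nucleotide exchange factor, differed by 1.86. ATF6B, an endoplasmic reticulum stress transcription factor, had the largest difference on the lower side of the rule, -2.62 (0.29 in controls, -2.33 with the inhibitor, adjusted p = 0.0707, 0.0124 with the trend). The long noncoding RNA gene ATP13A3-DT differed by -1.98. ZNF497 differed by -1.49 at one probe and by 0.03 at the other. CHMP4B, ATF6B, ATP13A3-DT, ZNF497 and RIT1 (-1.21), a RAS-related GTPase, came from the fixed rule, and CLSTN3 and ARHGEF25 were chosen after their values were seen. The CHMP4B probe lies on chromosome 20 from 32438804 to 32438863, the CLSTN3 probe on chromosome 12 from 7311467 to 7311526 and the ATF6B probe on chromosome 6 from 32083047 to 32083106 (hg19).

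No gene of the rule passed under limma's constant prior, and the adjusted p was 0.0600 for ATP13A3-DT, 0.104 for ZNF497 and 0.105 for RIT1. On the higher side, TMEM266, TULP1, AMBP, FAM30A, MEF2C, TEX19, NUP62CL, CRYM, AZGP1P1, CRMP1 and CCDC71 were not well above background on either control array. The bounds were at least 3.03-fold for CCDC71, at least 2.98-fold for CRYM, at least 2.53-fold for FAM30A and at least 1.84-fold for MEF2C, a myogenic transcription factor. The smallest bound was at least 1.43-fold for TEX19. The limma adjusted p ranged from 0.0526 for AMBP to 0.1796 for FAM30A. These p-values rest on control values not well above background. The standard error of AMBP was 0.065 with the constant prior and 0.349 with an intensity trend. On the lower side, DAB1, MTCL1, NRXN2 and CRLF3 were not well above background on either inhibitor array. DAB1, an adaptor of reelin signalling, was at least 2.62-fold lower and NRXN2, a neurexin, at least 2.15-fold lower. ZIM2 (-1.67), LINC00327 (-1.26) and OLFM1 (-1.22) were measured on all 4 arrays. The adjusted p of these genes ranged from 0.0990 for DAB1 to 0.227 for CRLF3.

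Further genes well above background on all 4 arrays and past the intensity-trend fit were chosen after their values were seen. They included MT1F (1.58), EML2 (1.56), DNAJC7 (1.47), LYRM9 (1.45), IGLON5 (1.32), NUTM2F (1.26) and AAGAB (1.23). Some were weak, with NUTM2F at -2.83 in controls. DNAJC7 is a co-chaperone of HSP70 and HSP90. On the lower side were RN7SL1 (-1.12), the RNA of the signal recognition particle, F7 (-1.06), PHF8 (-1.02, and -0.61 at its other probe), RCC1 (-1.02), RCOR2 (-0.94), CCDC177 (-0.83), FER1L4 (-0.78) and LINC00941 (-0.75). F7 encodes coagulation factor VII, PHF8 is a histone demethylase and RCC1 is the nucleotide exchange factor of Ran. Of the genes past the intensity-trend fit, 167 of 173 higher ones and 131 of 131 lower ones were well above background on all 4 arrays.

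Of 28 gene lists with enough measured members, camera with the preset correlation called 6 shifted up and 1 shifted down. The lists shifted up were the study list (median 1.02 with MET at its value below background, adjusted p = 2.25e-06), immediate early and heat shock genes, cell migration and chemokine receptors, NF-kappaB and inflammatory genes, hypoxia and glycolysis, and the unfolded protein and ATF4 response. Cytosolic ribosomal proteins shifted down. The study list was chosen on these samples, so its shift was given by that choice and is not independent evidence. With an estimated correlation none of the 7 passed (camera adjusted p = 0.437 for each). Their unadjusted camera p ran from 0.0318 to 0.109, and the shared value comes from the adjustment. That test also missed a simulated list moved by 0.3 under independent noise. It therefore cannot decide for or against any of these lists, here or where its value is repeated below. The number of lists called was 4 without control replicate 1, 3 without control replicate 2, 3 without inhibitor replicate 1 and 1 without inhibitor replicate 2. With the mean of all passing probes the hypoxia (adjusted p = 0.0606), unfolded protein (0.0830) and ribosomal (0.113) lists were lost, and with the replicate block as well (0.0776, 0.0875 and 0.0568). Median centring kept only the study list and the immediate early list of the 7 (0.0574 to 0.510 for the others).

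**Figure D2:**
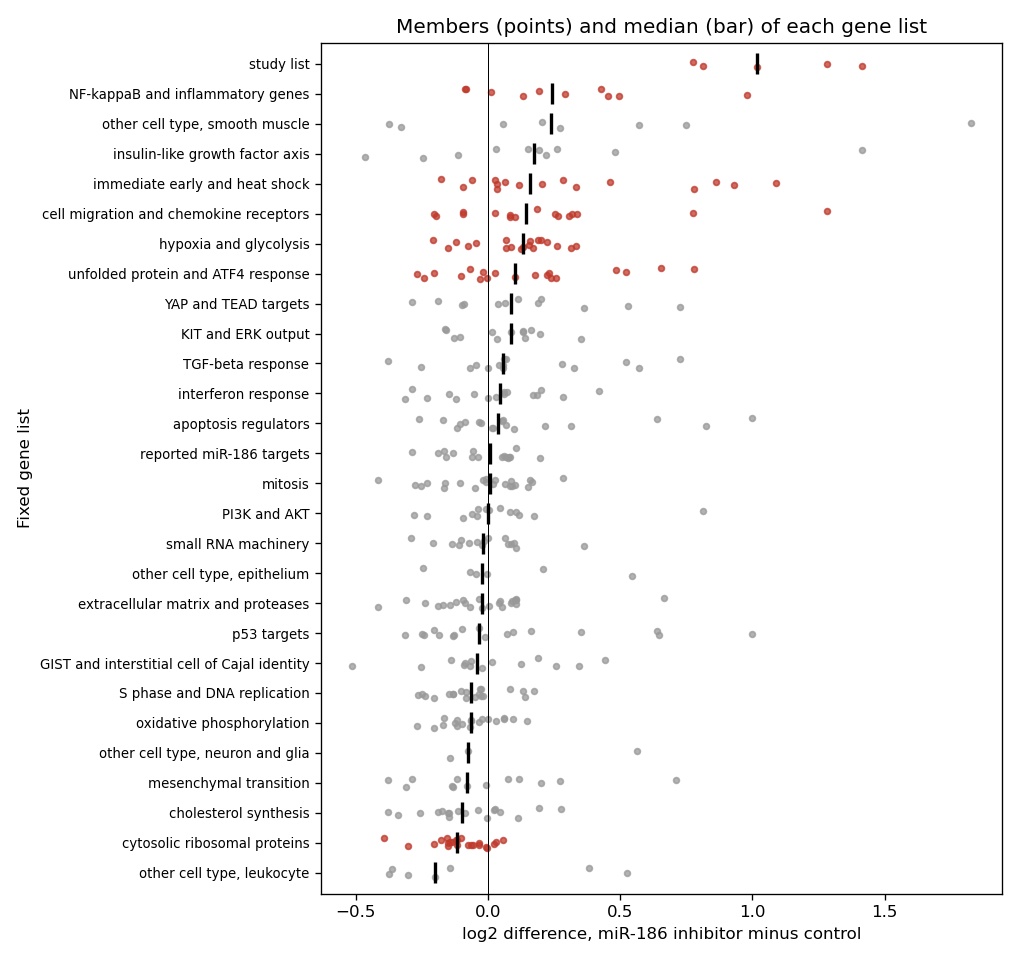
Log2 difference, inhibitor minus control (x axis), of each measured member (points) and the median (black bar) of the 28 fixed gene lists tested (y axis). Red marks the 7 lists past adjusted p 0.05 by camera with the preset correlation, and the study list has the highest median, 1.02.

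Immediate early and heat shock genes had 16 measured members with a median of 0.16 (adjusted p = 0.00241, or adjusted p = 0.437 with an estimated correlation). The members with the smallest p were MT2A (1.09) and MT1X (0.93), metal-binding metallothioneins, HMOX1 (0.86), which degrades haem, and ATF3 (0.78), a stress-induced transcription factor. The other ATF3 probes differed by 0.44, 0.07 and 0.40, and the mean over its passing probes by 0.42 (adjusted p = 0.140). MT2A, MT1X, HMOX1 and ATF3 passed with an intensity trend, and 5 members passed when adjusted over the list alone. JUN (0.46), an immediate early transcription factor, was the fifth of these, and the other 11 ranged from -0.18 for FOSB to 0.34 for JUNB, 8 of them above control. JUN, FOSB and JUNB were named after their values were seen. Without MT2A, MT1X, HMOX1 and ATF3 the other 12 members had a median of 0.05 (adjusted p = 0.211), a test also chosen after the values were seen. Without inhibitor replicate 2 the whole list had adjusted p = 0.0670. The unfolded protein and ATF4 response had 19 members with a median of 0.10 (adjusted p = 0.0428, or adjusted p = 0.437 with an estimated correlation). ATF3, PPP1R15A (0.52) and CHAC1 (0.49) passed when adjusted over the list alone, and SDF2L1 (0.26) did not. Without any 1 of the 4 arrays the unfolded protein list no longer passed, with adjusted p from 0.0806 to 0.122.

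Cell migration and chemokine receptors had 16 members with a median of 0.14 (adjusted p = 0.0327, or adjusted p = 0.437 with an estimated correlation). CXCR4, MET, CXCL12 (0.34), the ligand of CXCR4, and RAC1 (0.31) were among the 5 members past adjustment over the list alone. CXCR4 and MET are also genes of the study list, and without them the adjusted p was 0.166. NF-kappaB and inflammatory genes had 10 members with a median of 0.24 (adjusted p = 0.0364, or adjusted p = 0.437 with an estimated correlation). ICAM1 (0.98), an adhesion molecule, RELB (0.46) and TNFAIP2 (0.43) passed when adjusted over the list alone, while IL6 (0.49) did not. The migration list was lost without control replicate 2 (adjusted p = 0.0806) or inhibitor replicate 2 (adjusted p = 0.139). The NF-kappaB list was lost without inhibitor replicate 1 (adjusted p = 0.0859) or replicate 2 (adjusted p = 0.117), and with no filter on dim probes (adjusted p = 0.452).

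Hypoxia and glycolysis genes had 19 members with a median of 0.13 (adjusted p = 0.0428, or adjusted p = 0.437 with an estimated correlation), and none passed when adjusted over the list alone. The members with the smallest p were HK2 (difference 0.33), PDK1 (0.31), SLC2A1 (0.23) and GAPDH (-0.21). Leaving out any 1 array gave this list an adjusted p from 0.0882 to 0.122. Cytosolic ribosomal proteins had 23 members, 20 of them lower, with a median of -0.12 (adjusted p = 0.0364, or adjusted p = 0.437 with an estimated correlation). RPS14 was at -0.18 (0.14 and 0.01 at its other probes), RPS23 at -0.15 (0.05 at its other probe) and RPL8 at -0.15, and none passed when adjusted over the list alone. The list was lost with normexp (adjusted p = 0.590) and with no filter on dim probes (adjusted p = 0.0616). After quantile normalization the direction of the ribosomal list turned (adjusted p = 0.692), RPS23 included (0.01). Leaving out any 1 array gave it an adjusted p from 0.0719 to 0.122.

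Lists of signalling and identity did not pass as lists. GIST and interstitial cell of Cajal identity genes had a median of -0.04, a mean of 0.01 and an upward test over 14 members (adjusted p = 0.951). HAND1 (-0.51), a transcription factor, and KIT (0.34, but -0.02 and 0.02 at its other probes) passed when adjusted over the list alone. PRKCQ was at -0.25 and GPR20 at 0.26. KIT and ERK output had a median of 0.09 over 13 members (adjusted p = 0.237), with SPRY2 at 0.35, ETV5 at 0.16 and SPRY4 at 0.14 (-0.02 at its other probe) and no member past adjustment over the list alone. The insulin-like growth factor axis had a median of 0.17 over 10 members (adjusted p = 0.194). IGFBP3 and IGFBP2 (0.48) passed when adjusted over the list alone, and IRS1 (-0.47) and IGF2 (-0.25) did not. PI3K and AKT genes had a median of 0.00 and a mean of 0.04 over 14 members (adjusted p = 0.752). AKT2 (0.81, but -0.28 and -0.23 at its other probes) passed when adjusted over the list alone. AKT1 (-0.23), TSC2 (-0.28) and PIK3R1 (0.18) did not.

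Mesenchymal transition genes had a median of -0.08 over 13 members (adjusted p = 0.791), with S100A4 (0.71), ITGA5 (-0.29) and ITGB1 (0.27) past adjustment over the list alone and SNAI2 (-0.38) not. Extracellular matrix and protease genes had a median of -0.02 over 23 members (adjusted p = 0.752), with COL1A1 at -0.31, LAMA4 at -0.24, FBLN1 at -0.19 (0.01 and -0.20 at its other bright probes) and MMP3 dim in controls. TGF-beta response genes had a median of 0.06 over 15 members (adjusted p = 0.217). ID1 (-0.38), TGFBI (0.52), CCN2 (0.72) and TAGLN (0.57, and 0.32 at its other probe) passed when adjusted over the list alone. YAP and TEAD targets had a median of 0.09 over 12 members (adjusted p = 0.194), with CCN2, F3 (0.53), CCN1 (0.36) and LATS2 (0.19) and no member past that adjustment.

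Proliferation and survival lists did not pass either. S phase and DNA replication genes had a median of -0.07 over 20 members (adjusted p = 0.194), with E2F1 at -0.26, MCM5 at -0.25, MCM4 at -0.24 and MCM3 at -0.21. Mitosis genes had a median of 0.01, a mean of -0.02 and an upward test over 22 members (adjusted p = 0.951), with MKI67 at -0.41, TOP2A at 0.28, UBE2C at -0.23 and KIF11 at 0.17. No S-phase or mitosis member passed when adjusted over its list alone. For p53 targets the median was -0.03, the mean 0.08 and the test upward over 17 members (adjusted p = 0.840). BAX (1.00, 0.58 at its other probe), GDF15 (0.65) and TP53I3 (-0.31) passed when adjusted over the list alone, and TP53INP1 (0.35, and 0.02 at its other probe) did not. Apoptosis regulators had a median of 0.04 over 18 members (adjusted p = 0.194). BAX, which promotes apoptosis, MCL1 (0.82), which opposes it, and CASP9 (0.31) passed when adjusted over the list alone, and BBC3 (0.64) did not.

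The remaining fixed lists did not pass either. Interferon response genes had a median of 0.05 over 16 members (adjusted p = 0.632), with IRF9 at 0.29, IFI6 at -0.15 and IFIH1 dim in controls. Cholesterol synthesis genes had a median of -0.10 over 18 members (adjusted p = 0.194), with MVD at -0.38, MVK at -0.34, SREBF2 at -0.26 and MSMO1 at 0.28. Small RNA machinery genes had a median of -0.02 over 16 members (adjusted p = 0.752), with CNOT7 at 0.37, CNOT1 at -0.29, TNRC6B at -0.21 and TARBP2 at -0.14. Oxidative phosphorylation genes had a median of -0.07 over 19 members (adjusted p = 0.222), with UQCRC1 at -0.27, NDUFS3 at -0.20, SDHD at 0.15 (0.34 and -0.08 at its other probes) and ATP5MC1 at -0.12. In these 4 lists no member passed when adjusted over the list alone.

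Markers of other cell types were given the same tests. Smooth muscle markers had a median of 0.24 over 8 members (adjusted p = 0.144), and 6 members passed when adjusted over the list alone. They included ACTG2 (0.75), TAGLN and SMTN (-0.37), and CNN1 was at least 2.16-fold higher. Leukocyte markers had a median of -0.20 over 7 members (adjusted p = 0.752), with CD14 (0.53) among the 2 members past adjustment over the list alone and CD68 (-0.20) and TYROBP (-0.36) not. Epithelial markers had a median of -0.02, a mean of 0.07 and an upward test over 6 members (adjusted p = 0.951). None passed, with EPCAM dim in 1 control, KRT14 at 0.21, KRT7 at -0.25 and KRT8 at -0.07. Neuron and glia markers had a median of -0.08, a mean of 0.11 and an upward test over 3 members (adjusted p = 0.752), with UCHL1 (0.56) past adjustment over the list alone and TUBB3 (-0.08) and SNAP25 (-0.14) not. Of the endothelial markers only CDH5 (-0.13) was measured, and that list was not tested.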

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

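Scaling to the spike-ins and the settings varied within the intensity-trend fit were chosen after seeing the data. For the genes called higher and lower (0 and 0), quantile normalization gave 6 and 0, median centring 227 and 463, normexp 143 and 80, the intensity trend 173 and 131, an adjusted p under 0.1 157 and 61, and a difference of at least 2-fold with no test 203 and 84. The other planned settings, among them the replicate block, the deposited value table and each array left out (0 to 0), gave 0 and 0. The median difference of all genes was -0.01, against -0.21 with median centring and 0.66 with scaling to the spike-ins, which called 14745 higher and 22 lower. The -0.21 does not account for the higher calls of median centring. The cause of those calls and of the other moves was not tested.

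In the intensity-trend fit (173 and 131), median centring called 134 higher and 448 lower, no filter on dim probes 28 and 1 (36396 genes tested) and the replicate block 25 and 4. Leaving out 1 array gave 0 to 596 higher and 0 to 1179 lower, the lone sample being assumed to vary like the other group. Same-numbered samples correlated at 0.06 across genes in their deviations from the group means, so they shared little of that deviation. Whether same-numbered samples were made together is not stated in the labels. Of the lists called (7), quantile normalization gave 6, no filter on dim probes 5, normexp 8, median centring 3, the mean of all passing probes 4, the replicate block 4, an estimated correlation 0 and fry, which does not compare a list with other genes, 14. Leaving out 1 array gave 1 to 4. The ribosomal list turned its direction after quantile normalization (adjusted p = 0.692), where its cause was not tested. Of 145 genes, 125 named by the rule and the others after their values were seen, 133 kept the sign of their difference under every alternative except scaling to the spike-ins, and none passed a test with the opposite sign there. Signal over background limits the dim genes: 11 of the 12 named higher genes have only a bound in controls. The slide or scan block and the site definitions were not run.

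Scaling to the spike-ins adds the same amount to the difference of every gene, so that 45 of the 145 named genes turned sign and 39 of them, all lower in the fit to the 75th percentile, passed as higher. Their differences were then, in order of the lists: YAP1 0.51, PTTG1 0.51, PAWR 0.48, PRKCQ 0.42, ITGA5 0.38, COL1A1 0.36, LAMA4 0.43, FBLN1 0.48, IGF2 0.42, AKT1 0.44, TSC2 0.39, E2F1 0.41, MCM5 0.42, MCM3 0.47, MCM4 0.43, MKI67 0.26, UBE2C 0.44, TP53I3 0.36, IFI6 0.52, ID1 0.29, GAPDH 0.46, MVD 0.29, MVK 0.33, SREBF2 0.41, CNOT1 0.38, TNRC6B 0.46, TARBP2 0.53, RPL8 0.52, RPS23 0.52, RPS14 0.50, UQCRC1 0.40, NDUFS3 0.47, ATP5MC1 0.55, KRT8 0.60, CDH5 0.54, CD68 0.47, SMTN 0.30, TUBB3 0.60 and FOSB 0.49. Which scaling holds for the cells was not tested.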

Other observations

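The gene classes and the tests of spike-ins, probe pairs and the seed match in this part were chosen after the values were seen, except the test of spot noise between probes, which was set before its result was seen but after a correlation between probes over all genes. How the outcomes of 4 of these tests are read was reworded, to be more cautious, after their results were seen. Metallothioneins stood out as a family: 8 of 9 measured genes were higher with the inhibitor, with a median difference of 0.93. MT1F differed by 1.58, MT1H by 1.18, MT2A by 1.09, MT1L by 0.96, MT1X by 0.93 (1.02 at its second probe), MT1B by 0.84 and MT1A by 0.60, while MT1E (0.42) varied between arrays and MT3 differed by -0.13. Relative to all genes the family's median lay between 0.93 and 0.95 with 75th percentile scaling, quantile normalization and normexp, and 6 members passed the intensity-trend fit. Camera gave the family adjusted p = 5.39e-07 with the preset correlation and adjusted p = 0.0560 with an estimated correlation, adjusted over the gene classes of this part alone. The family was picked on these same values, so its p is not independent evidence. These genes are near-identical copies, so one probe can read several of them.

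Replication-dependent histone genes, whose mRNAs end in a stem-loop in place of a poly(A) tail, lay lower nearly throughout: 56 of 59 measured genes, with a median of -0.39 (95% bootstrap interval over genes -0.48 to -0.31). H3C10 (-0.73), H1-4 (-0.69), H3C4 (-0.64) and H2AC20 (-0.64) were among the 22 that passed the intensity-trend fit, and each of the 22 was lower. Camera gave adjusted p = 1.09e-17 with the preset correlation and adjusted p = 0.0560 with an estimated correlation, adjusted over the gene classes of this part alone. The class was picked on these same values, so its p is not independent evidence. Relative to all genes the median lay between -0.39 and -0.31 under the same settings. The replacement histone genes H3-3A (0.24), H3-3B (0.13) and H2AZ1 (-0.20), with polyadenylated mRNAs, had a class median of 0.05 over 8 genes.

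On these arrays S-phase genes did not lie as low as histone genes. The S-phase list had a median of -0.0650 (interval over genes -0.13 to -0.03), above the histone interval. Of its 20 members, 16 lay below control and 4 above. Both intervals are over genes of the same arrays and do not measure the spread between samples. They therefore cannot decide on a smaller share of cells in S phase that lowers histone and other S-phase mRNAs alike. A smaller fall in that share, tied more tightly to histone mRNA, was not tested and also stays open. A lower labelled amount of RNAs without a poly(A) tail cannot be told apart from a histone change: small nuclear RNAs had a median of -0.37, but their interval (-0.44 to 0.04) includes 0 over 17 genes. Relative to all genes that median was -0.36 with 75th percentile scaling and -0.14 after quantile normalization. RN7SK (-0.43), RNU2-2 (-0.37) and RN7SL1 (-1.12) lay on the lower side, and 157 of 230 small nucleolar RNAs did, with a median of -0.11. Of the 17 small nuclear RNAs, 5 lay above control and 12 below. At unadjusted p under 0.05 in limma, 3 were higher and 4 lower.

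The arrays carry E1A spike-in RNA added at labelling, and it differed between the groups. Relative to the 75th percentile, the 7 spike-in probes well above background were at 4.11 and 4.06 on the control arrays and 3.40 and 3.43 on the inhibitor arrays, a difference of -0.67, with single probes from -0.87 to -0.58. A brighter scan or stronger hybridisation of the inhibitor arrays as the only cause is argued against. Before scaling the spike-ins differed by -0.35 (SE 0.04 over probes) while the 75th percentile differed by 0.32. That SE is over probes of the same arrays and does not measure the spread between arrays. Unequal amounts of RNA or spike-in per tube cannot be excluded: arrays of a group lay within 0.0472 of each other, and the design does not separate handling from group. More polyadenylated RNA per ng of total RNA in the inhibitor samples also stays open, with non-polyadenylated RNAs at a median of -0.12, on the side it needs but well short of the spike-in difference. Differences in the report are therefore relative to each array's own 75th percentile, and an overall change in mRNA amount is not seen by it.

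Probes of one gene often disagreed. Bright probes here are well above background on all 4 arrays with a mean above 0. Over 1419 genes with 2 bright probes, differences taken from separate arrays correlated at 0.51 for the same probe and 0.29 between the probes of a gene. Spot noise alone is argued against by that gap of 0.22 (interval 0.17 to 0.27). Over all 4240 genes with more than 1 passing probe the correlations were 0.42 and 0.21, and as many simulated probe pairs sharing 1 difference gave 0.32 and 0.34. Probes reading different transcript forms or another gene's transcript cannot be told apart without transcript sequence, and 8 of 98 genes with both probes at unadjusted p under 0.05 had opposite signs, TTC28 (-0.63 and 0.27) among them. The probes of WLS (0.20 and 0.96), KIAA0040 (-0.09 and -1.05) and TNPO1 (0.86 and 0.17) lay on one side of 0 but differed in size.

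The last test concerned the microRNA itself. Probes carrying the 7-base match to the miR-186-5p seed, ATTCTTT, within their own sequence (161 of 22961) had a median difference 0.0176 above the other probes (interval -0.02 to 0.05). That ranked 24 among 42 rearrangements of the same bases. A release of mRNAs with a site inside the probed bases stays open, since the interval includes 0 and positive values, and sites elsewhere in the 3' UTRs were not searched.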
